A study of Mus musculus with 2 samples.

How the data were processed

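H3K4me2 was measured by chromatin immunoprecipitation and sequencing in stomach tissue of newborn mice, in 1 group with 2 biological replicates, both pools of males and females per the labels. The 4 peak lists used were each in narrowPeak format on the mm10 assembly per the deposited file notes, namely peaks of replicate 1, peaks of replicate 2, peaks of both replicates pooled, and replicated peaks derived from the other 3 lists. The deposited signal value of each peak is an enrichment as the authors' peak caller gave it, and the control it is relative to is not named. The authors also gave for each peak a −log10 p and a −log10 q, which were used here only to set thresholds. The lowest −log10 p in each list was about 2. The peak caller, the aligner, the threshold and the role of the other files from which the authors derived the lists are not given in the sources used here. The lists hold no read counts, so depth per sample is unknown and precision is given as Wilson 95% intervals of peak or gene counts, which cover counting error only.

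Genes came from the GENCODE vM21 annotation of the same assembly and sequence from its genome FASTA. The 21853 protein-coding genes on chromosomes 1 to 19, X and Y with a protein-coding transcript were used, and 10 replicated peaks on other scaffolds were left out of the location counts. A gene was called marked when a peak overlapped 1 kb to either side of any annotated start of a protein-coding transcript. Breadth was the number of bases covered by peaks within 5 kb of the gene's main start, its 5′ end. Distal peaks lay more than 2 kb from any protein-coding start and were counted within 50 kb of the main start. Domains were replicated peaks joined across gaps of 1 kb or less, and the widest 5% of those with a start were compared with the rest. The CpG ratio was the observed to expected ratio within 500 bp of the start, in 10 deciles. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

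Replicates were compared by peaks that overlap by at least 1 bp, against 100 random placements of the peaks within their chromosomes, and by the correlation of signal over overlapping pairs. Gene lists were compared on the replicated peaks. Marking and membership of the widest domains were compared by two-sided Fisher's exact tests. Breadth and distal peaks were compared by two-sided permutation tests against 10000 random lists of the same size and CpG decile. The Benjamini-Hochberg adjustment ran over the 26 lists and the threshold was 0.05. The 26 lists were transcription factors, gland products, adhesion genes and forestomach genes of the epithelium, mesenchyme, smooth muscle, interstitial cells of Cajal, enteric neurons and glia, enteroendocrine cells, endothelium, immune cells, erythroid cells, mesothelium, pancreas, intestine, liver, skeletal and cardiac muscle, forebrain, germ line, photoreceptor and lens, 3 sets of Hox genes, ubiquitous genes and olfactory receptors. All symbols matched the annotation except 1, Ahsp, and 3 were matched through another name. Motifs were 17 consensus sequences, searched on both strands within 250 bp of distal peak centres and of GC-matched windows (within 2 percentage points) on the same chromosome outside all peaks, with 78 windows unmatched, and compared by Fisher's exact test with the adjustment over the motifs. Replicate differences by list were log2 ratios of mean breadth less that of all genes, placed among 10000 random lists of equal coverage, with no test.

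The gene lists, motifs, comparisons, most alternatives and the rule for naming genes were set before the data were examined. That rule names the genes with a start in the 12 widest domains, up to 4 members of each list with the most covered bases and up to 3 with none, up to 6 listed genes that differ most between the replicates, the 6 genes with the most distal peaks, and the Hox genes by count. Genes named outside the rule are those behind small counts, such as Afp, Cdx2, Gypa and Runx1, chosen after their values were seen. The alternatives were each replicate alone, the pooled list, the upper 50% of peaks by signal, other windows, gaps, overlap rules and control windows, CpG matching on or off, and matching on gene density. Peaks with q of 0.01 or lower, also with a 2 kb window, were added as an alternative after the data were examined. A permutation test that moved the genes of each Hox cluster together to 10000 other places, anchored at other protein-coding genes with or without equal gene density, was added then too, two-sided and adjusted over the 3 Hox lists.

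Interval functions were checked against direct counting in 50 random comparisons each, with 0 disagreements for 5 functions. The list tests were tested on simulated data of 20000 genes and lists of 20. Fisher's exact test recovered 200 of 200 planted lists and called 5 of 840 null lists, and the matched random lists recovered 195 of 200 and called 12 of 840. The planted effects were large and only upward, and simulated genes were independent. The recovery therefore does not give the power for the real lists. Gene clusters and the widest domains were not simulated. An ETS motif planted in 199 of 993 windows was found in 201, and 0 of 16 other motifs were called. Comparisons with other tissues, ages or marks, and with the control experiment that the labels name as possible, were not made here.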

Results

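H3K4me2, the dimethylated form of histone H3 lysine 4 that marks promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the stomach of newborn mice, at postnatal day 0. The design held 1 group with 2 biological replicates, each a pool of stomach tissue from males and females. Replicate 1 pooled 15 mice, and the labels give no number for replicate 2. With 1 group, the comparisons set the replicates against each other, and genes or regions against other genes or regions of the same tissue. Replicate 1 had 59496 peaks and replicate 2 had 48860, a mean of 54178 ± 7521 (SD, n = 2). These peaks covered 44.2 Mb and 43.9 Mb of the mm10 genome, a mean of 44.1 ± 0.167 Mb (SD, n = 2). The median peak was 364 bp long in replicate 1 and 539 bp in replicate 2. The list called on both replicates pooled held 51039 peaks, and the list of replicated peaks held 36311, which covered 45.4 Mb or 1.67% of the genome. Read numbers behind these lists are unknown here, so sequencing depth is unknown too. Values for a gene are given below as the mean of the replicates ± SD with n = 2, unless the replicated list is named.

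The first comparison asked how alike the pools of stomachs were. H3K4me2 peaks of replicate 1 overlapped a peak of replicate 2 in 66.5% of cases (39546 peaks, Wilson 95% interval 66.1 to 66.8%), against a mean of 2.92% for 100 random placements. Peaks of replicate 2 overlapped a peak of replicate 1 in 76.6% of cases (37420 peaks, interval 76.2 to 77.0%), against 3.44% for random placements. Shared bases made up 69.5% of all bases covered in either replicate. In the 3 highest deciles of signal, 100% of the peaks of each replicate had a partner in the other. Peaks without a partner were weaker, with a median signal of 3.43 against 7.34 in replicate 1 and 3.29 against 8.36 in replicate 2. They were also rarer at promoters, since 8.29% of them lay within 1 kb of a protein-coding start in replicate 1, against 49.8% of peaks with a partner. Across the 39546 overlapping pairs of peaks, signal had a Spearman correlation of 0.778 and, on the log2 scale, a Pearson correlation of 0.801. These correlations are across peaks, which are not independent replicates, and intervals cover counting error only.

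**Figure D1:**
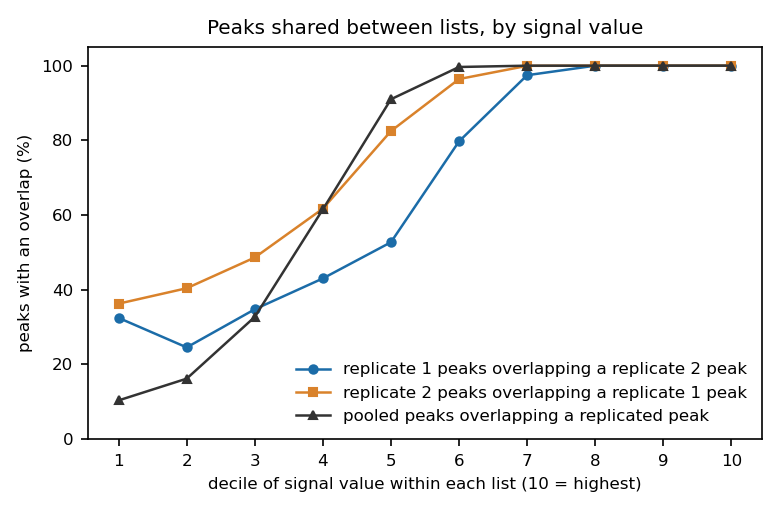
Percent of peaks that overlap another list (vertical axis) by decile of signal, lowest to highest (horizontal axis), with lines for replicate 1 in replicate 2, replicate 2 in replicate 1 and pooled peaks in the replicated list. In the lowest decile the values are 32.5%, 36.3% and 10.4%, and in the 3 highest deciles 100% in each line.

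All 36311 replicated peaks were identical in position to pooled peaks, and they made up 71.1% of the pooled list (Wilson 95% interval 70.7 to 71.5%). Their median signal was 8.63 and their median length 915 bp, against 2.84 and 238 bp for the remaining pooled peaks. Of the replicated peaks, 3015 (8.30%) had no overlapping peak in at least 1 of the replicate lists. These were weak, with a median signal of 3.4 against 10.3, and held 2.53% of the replicated bases.

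The next comparison asked where in the genome H3K4me2 lay. Promoters of protein-coding genes, taken as 1 kb to either side of a transcription start, held 16230 of the 36301 replicated peaks on chromosomes 1 to 19, X and Y. That share was 44.7% (Wilson 95% interval 44.2 to 45.2%), 18.9 times the 2.37% of the genome in such windows, and random placements reached at most 2.9%. Exons away from promoters held 5.35% of peaks, introns 25.9% and intergenic sequence 24.1%. Promoter peaks were longer and stronger, with a median length of 1604 bp and a median signal of 19.5, against 561 bp and 4.33 for introns and 606 bp and 5.2 for intergenic peaks. Promoter peaks held 61.7% of all replicated bases. By chromosome, the density was highest on chromosome 11, at 23.2 peaks per Mb. The X chromosome had 5.24 per Mb and the Y chromosome 6 peaks in all. Per protein-coding gene, chromosome 18 had the most peaks, at 2.20, against 1.73 on chromosome 11 and 0.946 on the X chromosome. The promoter share was 33.1% in replicate 1 and 38.5% in replicate 2, both below that of the replicated list, and it reached 73.8% among the upper 50% of replicated peaks by signal.

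Promoter marking followed CpG content. Of 21853 protein-coding genes, 14787 (67.7%, Wilson 95% interval 67 to 68.3%) had a replicated peak within 1 kb of an annotated start. The replicates marked 14949.5 ± 84.1 genes (SD, n = 2), and 14731 genes were marked in both. Marked genes had a median observed to expected CpG ratio of 0.700 around the start, against 0.165 for unmarked genes (two-sided permutation p = 0.0001, the smallest that 10000 resamples can give). In the lowest decile of CpG ratio 6.86% of genes were marked, in the fourth 52.0%, in the fifth 82.2% and in the highest 99.2%. Genes are not biological replicates, so this p describes genes of 1 tissue and not animals.

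Gene lists for cell types of the stomach, of neighbouring organs and of distant tissues were then compared with all other protein-coding genes, first by whether a start was marked. In 6 of the 26 lists more genes were marked than elsewhere, and each member of these lists was marked. They were 20 of 20 transcription factors of gastric epithelium, such as Sox2, Gata6, Foxa1 and Klf5, and 17 of 17 genes of epithelial adhesion, such as Cdh1, the cadherin of epithelial junctions, and the splicing regulator Esrp1. Further lists held 25 of 25 genes of stomach mesenchyme and patterning, such as Barx1, Foxf1 and Meis2, 24 of 24 smooth muscle genes, such as Myocd, Tpm2 and Myl9, 15 of 15 Hox genes, which set position along the body axis, of groups 1 to 5, and 25 of 25 ubiquitous genes such as Actb and Rpl7. The adjusted p in two-sided Fisher's exact tests was between 0.000366 and 0.00781 for these lists, against about 67.6% of other genes. In 9 lists, most of them of other tissues, fewer genes were marked. Liver had 5 of 20 genes marked (exact adjusted p = 0.000366), namely Afp, Ttr, Apoa1, Apoh and Trf, while Alb, the serum albumin gene, and Apob were not. Photoreceptor and lens genes had 5 of 20 marked (exact adjusted p = 0.000366), including the small heat shock gene Cryab but not Rho, the rod opsin. Skeletal muscle had 7 of 21 (exact adjusted p = 0.00372), with Myod1, Myf5 and Myog, its myogenic regulators, unmarked. Pancreas had 6 of 19 (exact adjusted p = 0.00424), and intestine 5 of 18 (0.00159), namely Cdx1, Cdx2, Vil1, Satb2 and Slc5a1, with the lactase gene Lct unmarked. Germ line genes had 3 of 22 marked, Dazl, Tex14 and Dmc1 (exact adjusted p = 2.1e-06), and olfactory receptors 4 of 1134.

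Blood and immune genes were also marked less often than other genes. Erythroid genes had 5 of 16 marked (exact adjusted p = 0.00866), namely Klf1, Epor, Gypa, Nfe2 and Tfrc, while Gata1 and the alpha globin genes Hba-a1 and Hba-a2 were not. Immune genes had 3 of 22 marked, Runx1, Ikzf1 and Coro1a (exact adjusted p = 2.1e-06), while Ptprc, the pan-leukocyte CD45 gene, and Csf1r, the macrophage receptor, were not. The immune list had 10 genes marked in replicate 1 and 5 in replicate 2, and the call ended with the peaks of replicate 1 alone (exact adjusted p = 0.0536). Genes that fall in no part of the rule for naming, such as Afp, Cdx2, Gypa and Runx1, were named after their values were seen.

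Among the 11 remaining lists no difference from other genes passed the test. Secreted and gland products of the stomach had 12 of 23 genes marked, 13 in replicate 1 and 17 in replicate 2. Muc1, the transmembrane mucin, Cldn18, the stomach claudin, and Lrig1, a stem cell regulator, were marked, while the surface mucin gene Muc5ac and the gastrokine genes Gkn1 and Gkn2 had no replicated peak within 5 kb of the start. Forestomach squamous epithelium had 14 of 22 marked, interstitial cells of Cajal 8 of 8, enteric neurons and glia 19 of 24, enteroendocrine cells 13 of 21, endothelium 16 of 21 and mesothelium 7 of 9. Cardiac muscle had 10 of 19 marked, forebrain neurons 20 of 24, Hox groups 6 to 8 had 8 of 8 and Hox groups 9 to 13 had 11 of 16. Forebrain genes passed the exact test with replicate 1 alone (exact adjusted p = 0.0242). With a 500 bp window cardiac muscle genes passed as less often marked (31.6%, exact adjusted p = 0.00476). Set against random lists of equal CpG ratio, 3 lists remained more often marked, gastric transcription factors (exact adjusted permutation p = 0.012), adhesion (0.0221) and smooth muscle (0.0026). At equal CpG ratio, 3 lists were less often marked, germ line genes (13.6% against 65.4%), Hox groups 9 to 13 (68.8% against 95.4%) and olfactory receptors (0.353% against 16.9%). At equal CpG ratio the calls for mesenchyme, Hox groups 1 to 5 and ubiquitous genes ended (adjusted permutation p 0.182, 0.175 and 0.182). Every gene of these lists was marked, against 90.5%, 84.8% and 92.4% in the random lists. No higher share was possible, so this test could not decide for these lists. The calls for immune, erythroid, pancreas, intestine, liver, skeletal muscle and photoreceptor genes ended too, with adjusted permutation p from 0.0635 to 0.823. Among the upper 50% of peaks by signal, the calls ended for gastric transcription factors, adhesion and Hox groups 1 to 5 (exact adjusted p 0.137, 0.155 and 0.214), and Hox groups 9 to 13 were marked less often, at 18.8% (0.00102). In that setting gland products (21.7%, exact adjusted p = 0.000327), forestomach (31.8%, 0.0116), enteroendocrine (28.6%, 0.00469) and cardiac muscle genes (21.1%, 0.000952) were also marked less often, while interstitial cells of Cajal and Hox groups 6 to 8 passed as more often marked (100% and exact adjusted p = 0.0384 for each). With 8 of 8 marked in the replicated list, these lists had reached the highest share they could, at an exact p of 0.0607.

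Breadth of H3K4me2 around the gene start also differed between the gene lists, which differ in kind of gene as well as in cell type. Stomach mesenchyme and patterning genes carried the widest coverage, 6630 bp within 5 kb of the start in the replicated list, against 2293 bp for random lists of equal CpG ratio in the same peaks. Random lists and tests of breadth used the replicated list throughout, and a mean ± SD is that of the separate replicates, here 6328 ± 134 bp (SD, n = 2). Foxf1, a transcription factor of gut mesenchyme, and Meis2 were covered over 9.96 kb of the 10 kb window, Barx1, a homeobox factor of stomach mesenchyme, over 9.65 ± 0.162 kb and Nr2f1, a nuclear receptor, over 9.58 ± 0.0679 kb. Gastric transcription factors had 4925 bp (replicates 4575 ± 104 bp) against 1922 bp, led by Gata6 at 8.65 ± 0.204 kb, Foxa1 at 8.65 ± 0.274 kb and Sox2, a factor of foregut epithelium, at 7.0 ± 0.356 kb. Smooth muscle genes had 4091 bp (replicates 3850 ± 169 bp) against 1661 bp, with the tropomyosin gene Tpm2 at 6.53 ± 0.221 kb and Myocd, the smooth muscle coactivator, at 5.17 ± 0.046 kb. Adhesion genes had 3530 bp (replicates 3385 ± 137 bp) against 1879 bp, with Esrp1 at 5.60 ± 0.112 kb and Cdh1 at 4.28 ± 0.499 kb. Each of these lists had an adjusted permutation p of 0.000325, from a p of 0.0001, the smallest that 10000 random lists can give.

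Smaller excesses of breadth were found for gland products, forestomach, enteric and ubiquitous genes. Gland products of the stomach had 1687 bp against 899 bp (replicates 1539 ± 180 bp, SD, n = 2, adjusted permutation p = 0.00598), with 6.46 ± 0.245 kb at Muc1, 0.248 ± 0.0757 kb at Gkn1 and 0.133 ± 0.188 kb at Muc5ac. Forestomach squamous genes had 1580 bp against 878 bp (replicates 1421 ± 2.38 bp, SD, n = 2, adjusted permutation p = 0.0135), led by Perp, a desmosome gene, at 4.41 ± 0.334 kb and Krt15 at 3.37 ± 0.293 kb, while Ivl, the involucrin gene, had none. Enteric neurons and glia had 2287 bp against 1721 bp (replicates 2134 ± 61.4 bp, SD, n = 2, adjusted permutation p = 0.044), with Hoxb5 at 9.33 ± 0.0728 kb, Hand2 at 7.91 ± 0.217 kb and Ednrb, the endothelin receptor of enteric precursors, at 4.34 ± 0.442 kb, and none at Plp1 or S100b. Ubiquitous genes had 3097 bp against 2478 bp (replicates 2941 ± 41.1 bp, SD, n = 2, adjusted permutation p = 0.0248), with Actb at 6.00 ± 0.216 kb. The gland product and forestomach calls ended without CpG matching (adjusted permutation p 0.981 and 0.826) and among the upper 50% of peaks by signal (0.155 and 0.571), with the forestomach list below its random lists in both. The enteric call rests on Hoxb5, also a member of Hox groups 1 to 5, since without it the mean was 1966 bp against 1684 bp (adjusted permutation p = 0.362), a test chosen after the values were seen. It also ended with replicate 2 alone (adjusted permutation p = 0.0953), with a 2 kb window, without CpG matching (0.0703) and among the upper 50% of peaks, and the 2 kb window ended the forestomach call too (0.0679).

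Coverage was narrower than in random lists for enteroendocrine, germ line and olfactory receptor genes. Enteroendocrine genes had 982 bp against 1692 bp (replicates 914 ± 17.3 bp, SD, n = 2, adjusted permutation p = 0.0219). Within that list the regulators Nkx6-3 (3.55 ± 0.625 kb) and Insm1 (3.23 ± 0.197 kb) were covered, while the hormone genes Gast, Ghrl and Sst, for gastrin, ghrelin and somatostatin, had no peak within 5 kb in either replicate. Germ line genes had 345 bp against 1488 bp (replicates 352.5 ± 43.1 bp, SD, n = 2, adjusted permutation p = 0.000867), and olfactory receptors 2.78 bp against 308 bp (adjusted permutation p = 0.000325). The enteroendocrine call ended with a 10 kb window (adjusted permutation p = 0.105) and without CpG matching (0.0517). No difference in breadth passed in the main setting for interstitial cells of Cajal, endothelium, mesothelium, immune, erythroid, pancreas, intestine or liver genes. None passed there for skeletal muscle, cardiac muscle, forebrain or photoreceptor genes. With a 2 kb window intestine (adjusted permutation p = 0.0375), skeletal muscle (0.0375), forebrain (0.0368) and photoreceptor genes (0.034) passed as narrower. Among the upper peaks by signal intestine (0.0173), skeletal muscle (0.025) and forebrain genes (0.0319) did. Without CpG matching immune, erythroid, pancreas, intestine, liver, skeletal muscle and photoreceptor genes did (0.00052 to 0.0135). The Cajal cell genes Kit, the receptor of these cells, and Kitl, its ligand, had 3.51 ± 0.132 and 4.74 ± 0.553 kb. The endothelial transcription factor gene Fli1 had 4.85 ± 0.0537 kb and the heart atrial light chain gene Myl7 had 2.41 ± 0.0255 kb. For Bcl11b, a zinc finger gene on the forebrain list, coverage was 7.02 ± 0.118 kb. The mesothelial genes Bnc1 and Wt1 had 1.83 ± 0.07 and 1.5 ± 0.214 kb, and Mafa, an islet regulator, had 2.67 ± 0.0587 kb. The immune gene Cd68 had 3.26 ± 0.0552 kb within 5 kb although its own start was unmarked in the replicated list.

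**Figure D2:**
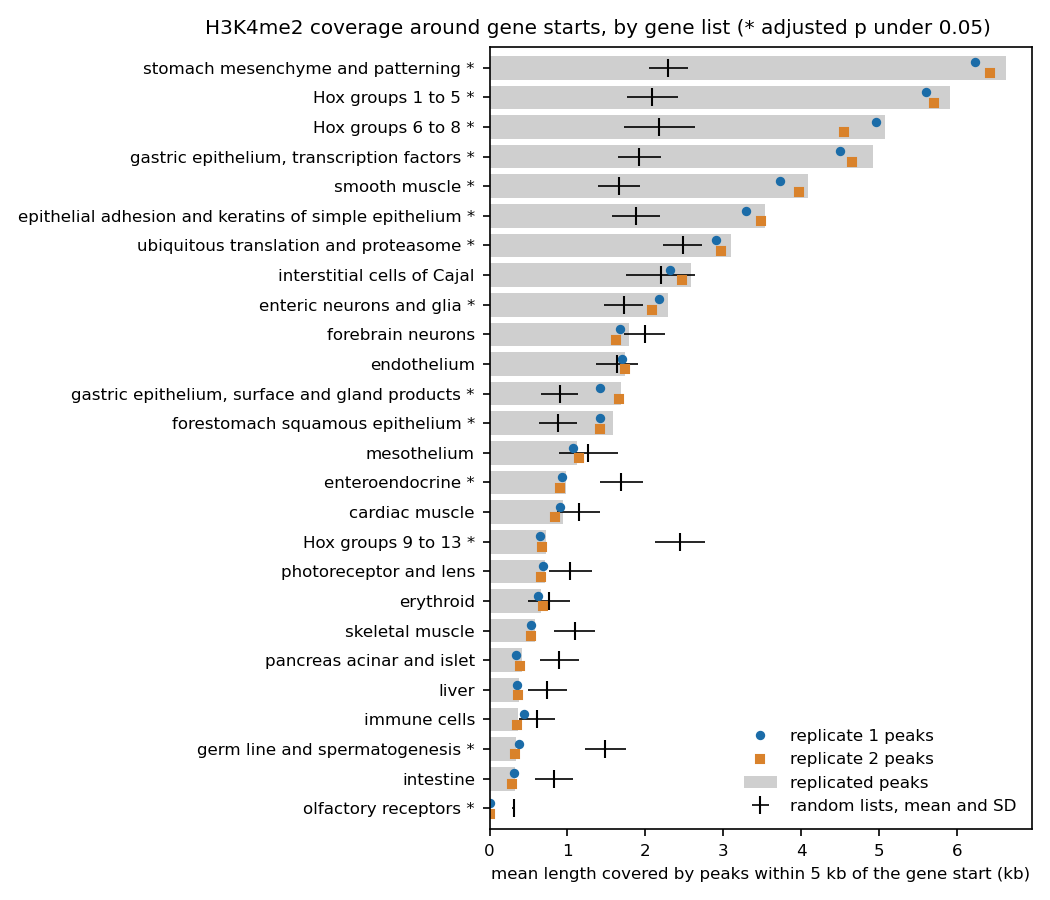
Mean kb covered by H3K4me2 peaks within 5 kb of the gene start (horizontal axis) for the gene lists, with bars for the replicated list, circles and squares for replicates 1 and 2, ticks with bars for the mean and SD of CpG-matched random lists, and asterisks for adjusted p under 0.05. Mesenchyme and patterning genes stand highest at 6630 bp and olfactory receptors lowest at 2.78 bp.

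Hox genes differed by group. In the replicated list groups 1 to 5 had 5911 bp covered within 5 kb of the start against 2090 bp in random lists of equal CpG ratio (replicates 5652 ± 70.8 bp, SD, n = 2), and groups 6 to 8 had 5077 bp against 2177 bp (replicates 4753 ± 291 bp). Groups 9 to 13, which pattern the posterior body, had 719 bp against 2445 bp (replicates 662 ± 17.6 bp). For all 3 lists the adjusted permutation p was 0.000325. In the replicated list coverage in the Hoxa cluster on chromosome 6 fell from 5.15 kb at Hoxa7 to 0.239 kb at Hoxa9. The Hoxa9 value is for the window around its main start (52231089). Replicated peaks at 52222806 to 52223114 and 52224074 to 52224467, towards the other end of the gene, lay outside that window. Another annotated start of Hoxa9 was marked, so the place of the boundary depends on the start used. On chromosome 11 coverage fell from 5.90 kb at Hoxb8 to 1.69 kb at Hoxb9. In the Hoxc cluster coverage went from 4.31 kb at Hoxc6 to 2.25 kb at Hoxc8 and 0.832 kb at Hoxc9. In the Hoxd cluster coverage was lower, with 1.44 kb at Hoxd1, 2.43 kb at Hoxd4, 1.5 kb at Hoxd8 and 1.91 kb at Hoxd9. It fell to 0.294 kb at Hoxd10, with 1.05 kb at Hoxd11, 0.567 kb at Hoxd12 and 1.43 kb at Hoxd13. Hoxb1 was low as well, at 0.98 kb. No replicated peak marked a start of Hoxa10, Hoxa11, Hoxc11, Hoxc12 or Hoxd12. The genes of a cluster share peaks, so these permutation p are too small. The annotated start of Hoxc5 lies at Hoxc10, and that of Hoxa3 between Hoxa6 and Hoxa7. Those of Hoxd3 and Hoxd4 lie side by side (74711927 and 74711929), so the Hoxd4 value holds for both. Without Hoxa3, Hoxc5 and Hoxd3 the mean for groups 1 to 5 was 6386 bp over 12 genes. This subset was chosen after the values were seen.

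**Figure D3:**
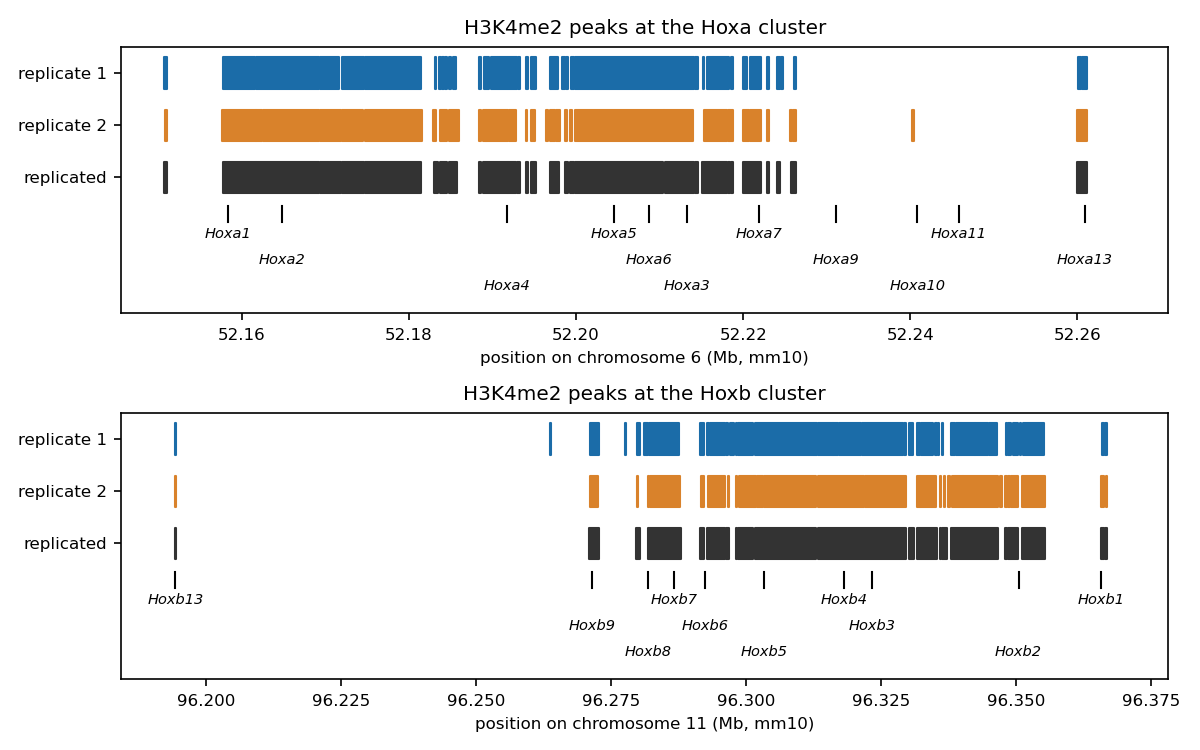
Maps of the Hoxa cluster (chromosome 6, 52145590 to 52270880) and the Hoxb cluster (chromosome 11, 96184316 to 96378256), with position on the horizontal axis in mm10 coordinates, boxes for peaks of replicate 1, replicate 2 and the replicated list, and ticks for annotated gene starts. The Hoxa region holds 37, 33 and 29 peaks and the Hoxb region 47, 31 and 22, and long peaks lie over Hoxa1 to Hoxa7 and Hoxb3 to Hoxb6.

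The widest domains, made by joining replicated peaks no more than 1 kb apart, included several over Hox genes and genes of the mesenchyme list. The longest spanned 48.5 kb over Hoxb3, Hoxb4, Hoxb5 and Hoxb6 on chromosome 11 (96298132 to 96346623). Next came 26.4 kb over Nr2f2, a nuclear receptor of mesenchyme and veins, on chromosome 7 (70344448 to 70370881), of which peaks covered 24.8 ± 0.484 kb (SD, n = 2). A domain of 23.9 kb lay over Rgmb on chromosome 17 (15807699 to 15831647), where the replicates differed most among the 12 widest, with 15.9 ± 2.72 kb covered (SD, n = 2). Further domains lay over Hoxa1, Hoxa2 and 5730596B20Rik (23.8 kb), over Ptch1, the Hedgehog receptor (21.9 kb), and over Hoxa3, Hoxa5, Hoxa6, Hoxa7 and Gm28308 (21.9 kb). The 12 were completed by Foxf1 on chromosome 8 (121072661 to 121091012, 18.4 kb), Meis2 (18.1 kb), Foxa1 on chromosome 12 (57534425 to 57551318, 16.9 kb), Zeb2 (16.9 kb), Meis1 (16.6 kb) and Tbx2 (15.9 kb). The widest 5% of the 13890 domains that hold a protein-coding start, 695 domains of at least 5.15 kb, held 803 of 14222 genes, or 5.65%.

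Genes in these widest domains included 19 of 24 mesenchyme and patterning genes (exact adjusted p = 1.3e-18) and 15 of 21 smooth muscle genes (8.5e-14). They also included 11 of 13 genes of Hox groups 1 to 5 (1.1e-11), 10 of 17 gastric transcription factors (2.7e-08) and 6 of 8 genes of Hox groups 6 to 8 (4.2e-06), in two-sided Fisher's exact tests. CpG content was not matched in these tests, and list members without a start in any domain were not counted. Gland products had 3 of 7, Muc1, Cldn18 and Lrig1 (adjusted p = 0.0229 in the exact test), and this call ended with the widest 10% of domains (0.148) and with the upper 50% of peaks (0.104). The remaining 20 lists did not pass, among them enteric genes with Hand2, Ednrb and Hoxb5 (3 of 16) and adhesion genes with Krt19, Esrp1 and Esrp2 (3 of 16). No list passed as having fewer genes in the widest domains than others. The test could hardly show fewer, since 5.65% of genes lay there and the lists were small. Even endothelium, with 0 of 15, and enteroendocrine genes, with 0 of 11, did not pass. With replicate 2 alone the adhesion list passed (exact adjusted p = 0.0393), and the enteric list passed with the upper 50% of peaks (0.0102) and with no joining across gaps (0.0371). Neighbouring Hox genes share a domain, so their exact p are too small.

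Distal peaks, those more than 2 kb from any protein-coding start, made up 16822 of the replicated peaks (46.3%). Their number within 50 kb of the start was counted for each gene, so neighbouring genes can share a peak. It was highest for Hox groups 1 to 5, with 7.20 per gene in the replicated list against 1.24 in random lists of equal CpG ratio. Hox groups 6 to 8 followed, with 6.38 against 1.25. Mesenchyme and patterning genes had 4.04 against 1.26 and adhesion genes 3.71 against 1.16, each of these 4 lists with an adjusted permutation p of 0.00052. Gastric transcription factors had 2.60 against 1.14 (adjusted permutation p = 0.00334), smooth muscle genes 2.46 against 1.15 (0.00357), forestomach genes 2.00 against 0.908 (0.00607) and pancreas genes 1.84 against 0.866 (0.0187). Hox groups 9 to 13 had 3.25 against 1.29 (adjusted permutation p = 0.0013), opposite to their low coverage at the start. Because neighbouring Hox genes share peaks, 19 distinct peaks were counted 52 times for this list. Groups 1 to 5 had 35 distinct distal peaks (2.33 per gene) and groups 6 to 8 had 29 (3.625 per gene). The higher count per gene of groups 1 to 5 thus rests on repeated counting. For the same reason the p of the Hox lists against scattered random genes are too small. With the genes of each cluster moved together to other places, a test chosen after the values were seen, the adjusted permutation p over the 3 Hox lists was 0.0378 for groups 9 to 13, 0.0009 for groups 6 to 8 and 0.0006 for groups 1 to 5. Forebrain genes had 2.13 against 1.22 (adjusted permutation p = 0.0258), a call that ended with either replicate alone (0.322 and 0.1). Olfactory receptors had fewer, 0.0882 against 0.571 (adjusted permutation p = 0.00052). Gland products had 1.52 against 0.898 (adjusted permutation p = 0.0899), which passed with replicate 1 alone (0.0203) and with replicate 2 alone (0.00325). With distal set at more than 5 kb from a start, 4 lists passed as higher, gastric transcription factors, adhesion, mesenchyme and Hox groups 1 to 5. Among the upper 50% of peaks 5 passed, the gastric transcription factor, mesenchyme, Hox 1 to 5, Hox 6 to 8 and ubiquitous genes, and a 20 kb window ended the calls for pancreas and Hox groups 9 to 13. With that window gland products (0.913 per gene, adjusted permutation p = 0.0117) and skeletal muscle genes (0.952, 0.017) newly passed.

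Counts per replicate were higher than in the replicated list, with 11 ± 1.18 distal peaks per gene of Hox groups 1 to 5 and 7.28 ± 0.226 per mesenchyme gene (SD, n = 2). Single genes with many distal peaks in the replicated list were Chd2, a chromatin remodeller gene, with 17 (19.5 ± 3.54 in the replicates, SD, n = 2), Trim8 with 16 (21 ± 1.41), Myh9, a nonmuscle myosin gene, with 15 (20.0 ± 2.83) and Lrig1 with 13 (24.5 ± 4.95). Btg2 and Btn1a1 also had 13. The keratin gene Krt15 had 10 and Foxf1 had 7.

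Sequence in distal peaks was searched for 17 consensus motifs of transcription factors. The search covered 16742 windows around the peak centre and as many windows of equal GC content outside peaks. Peaks at starts of other gene types were not left out, and control windows were not matched on CpG or repeat content. The CTCF motif, of the insulator protein, had the highest ratio in these windows, in 2.78% of windows against 0.418% of controls (ratio 6.64, exact adjusted p = 1.2e-72). The KLF motif had the smallest p and the widest difference in share, in 11.6% against 4.81% (ratio 2.4, exact adjusted p = 4.0e-114), and FOX was in 14.8% against 9.17% (ratio 1.61, exact adjusted p = 3.8e-56). HNF1 was in 0.179% against 0.0538% (ratio 3.33, exact adjusted p = 0.002), which rests on 30 windows against 9, and with replicate 2 alone on 48 against 8, a ratio of 6. Within 100 bp of the centre the CTCF ratio was 3.38 and that of HNF1 was 9, from 9 windows against 1. TEAD had a ratio of 1.43 (exact adjusted p = 7.7e-24), the muscle E-box 1.41 (6.6e-45), ETS 2.76 (1.5e-05), NFI 3.14 (0.0115) and AP-1 1.2 (5.0e-07). HNF4 had a ratio of 1.55 (exact adjusted p = 0.00333), CArG, the box bound by serum response factor in muscle genes, 1.17 (0.0354) and GATA 1.08 (0.00622). The SOX motif was less frequent, in 5.65% against 6.74% (ratio 0.839, exact adjusted p = 8.6e-05), and no difference passed for HOX-MEIS, p63, RFX or REST, in two-sided Fisher's exact tests. GATA turned to a ratio of 0.844 (exact adjusted p = 8.1e-12) against windows 5 kb from the same peaks, which were not matched on GC content (45.3% against 51.5% in peaks). Among the upper 50% of peaks the GATA, HNF4 and SOX calls ended, with ratios on the other side of 1 (0.935, 0.786 and 1.05). None of these ratios passed there (exact adjusted p 0.745, 0.902 and 0.902). The HNF4, HNF1, NFI and AP-1 calls also ended under at least 1 alternative, as did CArG, with replicate 1 alone among others (exact adjusted p = 0.0718), where HOX-MEIS passed as less frequent (0.0414). HOX-MEIS also passed as less frequent against the windows 5 kb from the same peaks (ratio 0.722, exact adjusted p = 0.004). With replicate 2 alone the HOX-MEIS ratio went the other way, at 1.17 (249 against 212 windows, exact adjusted p = 0.112).

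**Figure D4:**
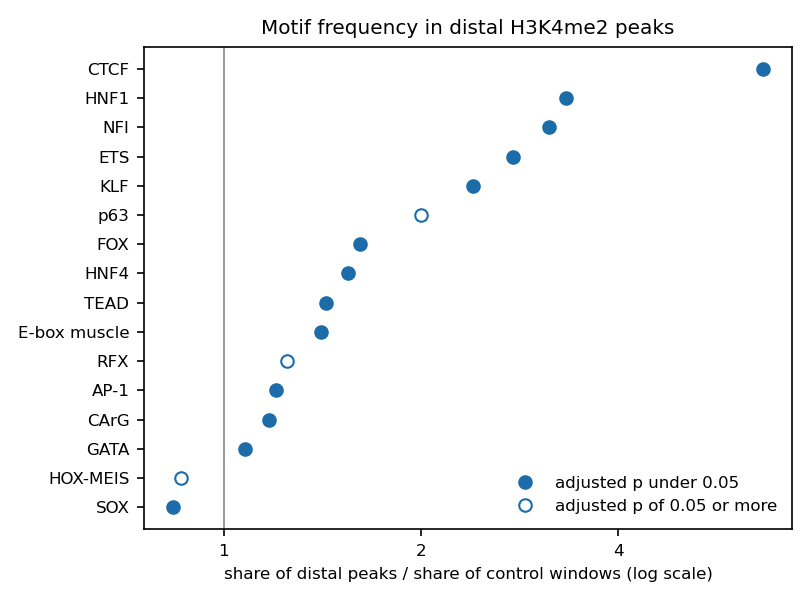
Ratio of the share of distal H3K4me2 windows with a motif to that of control windows of equal GC content (horizontal log axis) for 16 motifs, with a line at a ratio of 1 and the REST motif not drawn because no control window held it. CTCF stands highest at 6.64 and SOX lowest at 0.839.

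The last comparison asked whether gene lists differed in coverage between the replicates, without a test because each side holds 1 library. Coverage of gland product genes was higher in replicate 2, by 0.21 on the log2 scale beyond the 0.03 of all genes, with 18 genes higher in replicate 2 and 3 in replicate 1. Among these Cldn18 had 3.03 kb in replicate 1 and 4.05 kb in replicate 2. Immune genes were lower in replicate 2 (log2 -0.33), with 2 genes higher in replicate 2 and 10 in replicate 1, and Hox groups 6 to 8 were lower too (log2 -0.15, 1 gene against 7), with Hoxb8 at 6.29 and 5.14 kb and Hoxc6 at 4.11 and 3.17 kb. These lists lay at percentiles 99.98, 0.47 and 0.08 among 10000 random lists of equal coverage, and the other 23 of the 26 lists lay within the middle 95%. Gastric transcription factors differed by 0.02 and mesenchyme genes by 0.01. Other listed genes with large differences were Krt18 (2.60 and 3.91 kb), Esam, an endothelial adhesion gene (3.10 and 4.12 kb), and Krt8 (3.51 and 2.56 kb). With a 2 kb window 5 lists lay outside the middle 95% and with a 10 kb window 8, and with 2 kb the gland products lay inside, at percentile 92.81, while the immune genes lay at 0.03 (log2 -1.02, 0 genes higher in replicate 2 and 9 in replicate 1). With peaks of q of 0.01 or lower the immune genes lay inside, at percentile 7.65. Hox groups 6 to 8 stayed outside in every setting tried, at percentiles from 0.01 to 2.09, but neighbouring Hox genes share peaks and are not separate observations.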

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

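Alternatives with peaks of q of 0.01 or lower, alone or with a 2 kb window, and the enteric list without Hoxb5 were chosen only after the data were seen, and the others before. Over the settings tried, 82 of the values that answer a comparison kept their call, stayed within their spread or, for counts, within 1.5 times, 7 counts were lower and 8 higher by more than that, and 30 shares or correlations moved. For single lists and motifs 1029 values kept their side of the threshold or stayed within their spread, 57 no longer passed, 34 newly passed, 29 moved and 10 reversed. Reversed means that a value changed side, whether or not it passed the test in either setting. The cause was not tested, except where a stricter overlap or a smaller list of peaks lowers a share by its construction. Overlap of replicate 1 with replicate 2 and the converse were 62.1% and 72.1% with 50% of either peak, 48.7% and 59.3% with 50% reciprocal overlap, 81.5% and 95.8% for the upper 50% of peaks by signal in each list, 74.9% and 72.6% with the same number of peaks, 73.8% and 77.9% with q of 0.01 or lower, and 69.5% as shared over all bases. The rank correlation was 0.895 for summits within 500 bp, 0.789 for −log10 p and 0.794 for the upper 50%. Leaving out each replicate in turn gave promoter shares of 33.1 to 38.5%, marked genes of 68.1 to 68.7% and 1 to 2 motifs lower. The pooled list gave 34.3% promoter peaks and 68.8% marked genes. With the upper 50% of peaks the replicated share was 99.9%, promoter peaks 73.8%, marked genes 62.1%, lists lower by marking 14 (from 9) and by breadth 7 (from 4), lists higher by distal peaks 5 (from 10), motifs higher 6 and lower 0 (from 12 and 1). In that setting Hox groups 9 to 13 reversed (18.8% marked), from no difference to marked less often. Forestomach breadth (556 bp) and distal peaks (0.182), and GATA (0.935), HNF4 (0.786) and SOX (1.05) also changed side, but none of them passed there. Promoter shares were 31.9% with a 500 bp window, 51.9% with 2 kb and 52.7% with all gene types, and marked genes were 66.9%, 68.5% and, with 1 main start per gene, 64.7%. Random lists of equal CpG ratio gave 3 lists higher and 3 lower by marking, with Hox groups 9 to 13 reversed (68.8%). By breadth 8 lists were lower with a 2 kb window and 10 without CpG matching, where forestomach reversed (1580 bp), and the enteric call ended without Hoxb5 (1966 bp). A distal limit of 5 kb left 4 lists higher. Windows 5 kb from the same peak gave 3 motifs lower, with GATA reversed (0.844), and windows of 100 bp reversed CArG (0.981). Replicate differences put 5 lists outside the middle 95% with a 2 kb window, 8 with 10 kb and 1 with a 2 kb window and q of 0.01 or lower. No paired analysis was possible because the design holds 1 group, and unknown depth leaves open how many weak regions either replicate missed.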

Other observations

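The gene families below, the test of split regions, the tests of chance among the lists, the tests with peaks of q of 0.01 or lower and the tests with moved Hox clusters were chosen only after the data were seen. Outside the 26 lists, protein-coding genes were grouped by symbol stem, and 7 of 241 families with at least 8 genes were overrepresented in the widest 5% of H3K4me2 domains by two-sided Fisher's exact tests. Frizzled genes, receptors for Wnt ligands, had 6 of 10 in such domains (exact adjusted p = 0.000831), namely Fzd2, Fzd4, Fzd5, Fzd7, Fzd8 and Fzd10, against 5.17% of other genes. Genes with the stem Pcdh, a part of the protocadherins, had 5 of 10 (exact adjusted p = 0.00926), namely Pcdh7, Pcdh10, Pcdh17, Pcdh18 and Pcdh19. Protocadherins of the stem Pcdhb were counted apart, and only 2 of 22 of them were marked at a start. Sox genes had 5 of 12 (exact adjusted p = 0.0133), namely Sox4, Sox6, Sox11, Sox12 and Sox21. Collagen genes, which encode the fibres and basement membranes of connective tissue, had 8 of 39 (exact adjusted p = 0.0367), among them Col1a1, Col3a1, Col4a1, Col4a2, Col5a1 and Col6a3. The Bcl (6 of 17), Zbtb (8 of 40) and Arid (4 of 10) stems also passed, with exact adjusted p of 0.0119, 0.0367 and 0.0411. A shared stem does not make a family by descent. Only genes with a start in a domain were counted, and CpG content was not matched.

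By marking of the start, 107 families with at least 20 genes were compared, of which 46 were marked more often than other genes and 30 less often. Vomeronasal receptor genes had 1 of 331 marked (exact adjusted p = 9.5e-180), and keratin-associated proteins 0 of 57, beta defensins 0 of 42, secretoglobins 0 of 34 and prolactin relatives 0 of 25. Cytochrome P450 genes had 29 of 99 marked. Mitochondrial ribosomal protein genes of the large subunit had 49 of 49 marked, the DEAD-box genes 36 of 36, the Rab genes 68 of 69 and the Zfp zinc finger genes 344 of 394. CpG content was not matched in these comparisons.

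Replicate 1 had 10636 more peaks than replicate 2 although the covered length was nearly equal. Division of wide regions into more pieces would add peaks that overlap the other replicate, and these made up 20.0% of the surplus (2126 peaks), which argues against it as the main source. Weak calls, those with p above 1e-05, may account for most of the rest. At p of 1e-05 or lower the surplus was 995 peaks, 9.36% of the surplus over all peaks. Most of the surplus did not lie next to the limit, since 79.5% remained at −log10 p of at least 3 and 42.6% at 4. At −log10 p of at least 7 replicate 1 had fewer peaks than replicate 2, 27901 against 29432. The labels give no sequencing depth, which stays open, and no biological explanation was tested because the design holds 1 group.

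Coverage differed between the replicates for gland product genes, higher in replicate 2, and for immune genes, higher in replicate 1, as for Hox groups 6 to 8, which lay at percentiles from 0.01 to 2.09 in all settings and were not tested for a source. With peaks of q of 0.01 or lower the gland products stayed at percentile 99.99 (log2 0.21). This argues only against peaks with q above 0.01 as their source within 5 kb. The filter kept 80.5% of the peaks of replicate 1 and 89.1% of those of replicate 2. Among peaks without a partner it kept 57.7% and 69.3%, so weak peaks that passed it stay open as a source. Within 2 kb the list lay at 92.81 with all peaks. The immune list moved to percentile 7.65 (log2 -0.17) with those peaks, and within 2 kb from 0.03 (log2 -1.02) to 6.89 (log2 -0.34), so weak peaks may account for it. Chance stays open for both, since the doubled share of random lists as far out, times 26 lists, was 0.0104 and 0.244 within 5 kb and 0.0052 and 0.858 within 10 kb but 1 and 0.0156 within 2 kb, and random lists of genes do not measure how single libraries vary. No biological explanation was tested, since the design holds 1 group.

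Hox groups 9 to 13 had more distal peaks than random lists but less coverage at the start. The excess ended with a distal limit of 5 kb, at 1 per gene (adjusted permutation p = 0.893). It also ended within 20 kb, at 0.5625 per gene, and among the upper 50% of peaks, at 0.5625 (adjusted permutation p = 0.412). What follows concerns the main setting alone. Of the 19 distinct distal peaks counted for them, 16 (84.2%) also lay within 50 kb of a Hox gene of groups 1 to 8. Whole clusters moved to other places gave 65.6% on average (one-sided permutation p = 0.261, unadjusted). This used the 9699 placements with a distal peak near groups 9 to 13. The layout therefore keeps open whether the excess comes from the neighbours. Repeated counting of these peaks, 52 times over 16 genes, is narrowly argued against as the whole source, since the clusters moved together to other places had 1.06 per gene against 3.25 (adjusted permutation p = 0.0378). Low gene density is narrowly argued against too, with 1.16 per gene at places of equal density (adjusted permutation p = 0.041), but neither test matched CpG content and both were adjusted over 3 Hox lists alone. No biological explanation was tested for this pattern.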
